A study of Mus musculus with 2 samples.

How the data were processed

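DNase-seq had been done on heart tissue of 2 male B6CASTF1/J mice aged 36 days, labelled biological replicates 1 and 2, which were treated as 1 group with n = 2. Per the labels, coordinates are on mouse assembly mm10. For each library the authors deposited 2 peak lists, 1 footprint list and 1 list of per-base false discovery rates (FDR), all made per library and not from pooled replicates, per the file headers and descriptions. The aligner, peak caller, footprint caller and their versions are not given in the sources used here.

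The deposited peak lists hold a signal value per peak that is never negative. It came out as a whole multiple of 1 step in 100% of peaks of each library. The tolerance was 0.01 of a step up to 100 steps and grew in proportion to height above that, so the highest peaks were hardly tested. A count scaled by 1 factor per library would give such steps, but the scaling is not stated. Values of the 2 libraries were therefore compared only with this limit in mind, and the deposited peak lists give no p-value per peak. Each of the peaks of the longer list touched a base with a deposited per-base FDR, a p-value type of measure, of at most 0.05, and each of the shorter list (80908 and 77627 peaks) a base at 0.001 or below. The longer list was used throughout and the shorter as an alternative. The FDR lists deposited by the authors name 47.3 Mb and 40.9 Mb of bases under 0.05. Footprints carry the constant deposited FDR threshold of 0.01 in place of a value per footprint.

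Annotation was GENCODE M21 and sequence the GRCm38.p6 reference, which is the mm10 assembly; all coordinates fitted within its chromosome lengths. Chromosomes 1 to 19, X and Y were used. Peaks of the libraries were called shared when they overlapped by at least 1 bp, and joined into regions whose value per library was that of its highest peak. Expected overlap came from 100 random placements of one list within its chromosomes. A peak stood in one library alone when the other library had neither a peak nor a base under FDR 0.05 there. Footprints were compared with footprints moved at random within peaks. Location was taken at the peak centre, with promoter (within 1 kb of a TSS of a protein-coding gene) before exon, intron and intergenic, and exact binomial 95% intervals. Exons and introns were those of protein-coding genes, so DNA called intergenic can hold genes of other types.

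The 22 gene lists (348 entries, all matched to symbols, 333 distinct genes) and 30 consensus sequences were fixed before the data were examined, as were the tests and most alternatives. They cover cardiac muscle, its metabolism, chambers and stress genes, other cell types of the heart, other tissues, and housekeeping, circadian and immediate early genes. Some genes stand in more than 1 list. A gene had a promoter peak when a peak lay within 500 bp of any annotated TSS in both libraries, and its promoter value is that of the highest such peak per library. Lists were compared with all other protein-coding genes by two-sided Fisher's exact test. Distal peaks were regions over 1 kb from any TSS of a protein-coding gene, counted in the gene body plus 50 kb on each side, and compared with 10000 random lists matched on domain length in 20 bins by a two-sided permutation test, whose smallest p is 0.0002. Domains of neighbouring genes overlap, so 1 region can be counted for several genes. Consensus matches on both strands were counted in footprints of both libraries, widened by 5 bp on each side (4525 kb), and in the rest of the shared regions (21017 kb), and compared by an exact binomial test, with 10 shuffles of each consensus as a further background. Benjamini-Hochberg adjustment ran over the 22 lists or 30 motifs, with 0.05 as the threshold. X and autosomal median values were compared by a permutation test with 100000 resamples.

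Genes were named by a rule fixed before the data were examined. It took the up to 3 members of each list with the highest mean promoter value and up to 2 without a promoter peak in either library, the 10 genes with the highest promoter values and the 10 with most distal peaks, and the 3 highest peaks of one library alone. Motifs at the 5 highest and 5 lowest ratios were named. MEF2, TEAD and NKX2-5, the highest regions, and genes named in the closing part outside this rule were chosen after their values were seen.

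On simulated data with 21911 genes, the distal test called 6% of 50 lists of 20 random genes with no change, 22% of lists whose counts were raised 1.5-fold, 56% at 2-fold and 90% at 3-fold. The promoter test called 2% of 200 unchanged lists, 20% of lists with a simulated share of 0.8 and 94% of lists with a share of 0.95. The consensus search found all 500 planted matches. Lists of 20 genes thus often miss distal changes of 2-fold and less and promoter shares near 0.8, and shorter lists were not simulated. The adjustment over 22 lists, which can only lower these shares, and the overlap of neighbouring domains were not simulated either.

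The depth in reads is unknown. The step of the values was 0.00639 in replicate 1 and 0.00594 in replicate 2, so that the median peak was 107 and 122 steps high, which bounds the counting error only if 1 step is 1 cut. The planned steps differed in 2 places. Neither deposited list holds wider hotspot regions, so the alternative list was the shorter peak list. The footprint lists hold no statistic to rank by, so the stricter footprint setting was not run and footprints of 10 bp or wider were used. Alternatives were the upper 50% of peaks by value, the shorter list, other windows and domains, other overlaps, equal list lengths, autosomes only, other backgrounds and each library left out in turn. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.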

Results

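DNase-seq, which maps DNA that is open to cutting by the enzyme DNase I and so marks promoters, enhancers and other regulatory DNA, was available for heart tissue of 2 male B6CASTF1/J mice aged 36 days. B6CASTF1/J mice are first-generation hybrids of a laboratory strain and the wild-derived strain CAST/EiJ. The labels number the libraries as biological replicates 1 and 2 of 1 group, so the comparisons were between the hearts, between gene groups and between parts of the genome. The longer deposited peak list held 126037 peaks in replicate 1 and 125145 in replicate 2, a mean of 125591 ± 631 (SD, n = 2). These peaks covered 27.3 Mb in replicate 1 and 24.9 Mb in replicate 2, about 1.00% and 0.915% of the genome. The number of sequenced reads was not stated. Peak values were whole multiples of 1 step in each library, within a tolerance that grew with height. The median peak had a value of 107 steps in replicate 1 and 122 steps in replicate 2. Values ± SD in what follows are over the 2 hearts, and p-values are over genes, regions or bases, so they describe these 2 hearts and not a population of animals.

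The first question was which regions were open in both hearts. Regions of repeated or poorly mapped sequence were not filtered out here, so the highest values need not reflect openness alone. The region with the highest value lay outside protein-coding genes on chromosome 17 (39846781 to 39846920, mm10), with a peak value of 80.3 ± 7.24 (SD, n = 2). Whether it lies in a gene of another type, or is present in many copies, was not tested. An exon of Lars2, the mitochondrial leucyl-tRNA synthetase gene, held the next highest region on chromosome 9 (123461901 to 123462120), at 51.6 ± 3.05. The highest promoter values belonged to Dynlt1b, a dynein light chain gene, at 39.3 ± 0.725, and to Trpm8 and Hjurp, 2 divergent neighbours on chromosome 1 that share 1 region, at 38.2 ± 2.06. They were followed by the nuclear pore gene Nup107 at 30.2 ± 1.38, Rragc at 25.6 ± 4.92, Wwox at 25.6 ± 4.16, Zswim1 at 25.5 ± 11.1, Nup153 at 25.2 ± 5.21, the calcineurin subunit gene Ppp3ca at 25.05 ± 4.17 and Bahcc1 at 24.7 ± 3.10. The Zswim1 promoter differed most between the hearts among these 10 genes, with 17.7 in replicate 1 and 33.3 in replicate 2.

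Of the peaks of replicate 1, 75.9% overlapped a peak of replicate 2 by at least 1 bp, and of the peaks of replicate 2, 77.7% overlapped a peak of replicate 1. The mean was 76.8% ± 1.31 (SD, n = 2), against 2.11% for peaks moved at random within their chromosomes. Overlap rose with the peak value in both hearts. In the fifth of peaks with the lowest values 38.8% and 42.2% were found in the other heart, and in the fifth with the highest values 99.6% and 98.8%. Joining overlapping peaks gave 92536 regions open in both hearts. Across these regions, which are not independent replicates, the log2 values of the hearts had a Pearson r of 0.951 and a Spearman rho of 0.935. The log2 ratio of replicate 2 to replicate 1 had a median of 0.03 and an SD of 0.46, and 96.2% of regions differed by less than 2-fold.

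**Figure D1:**
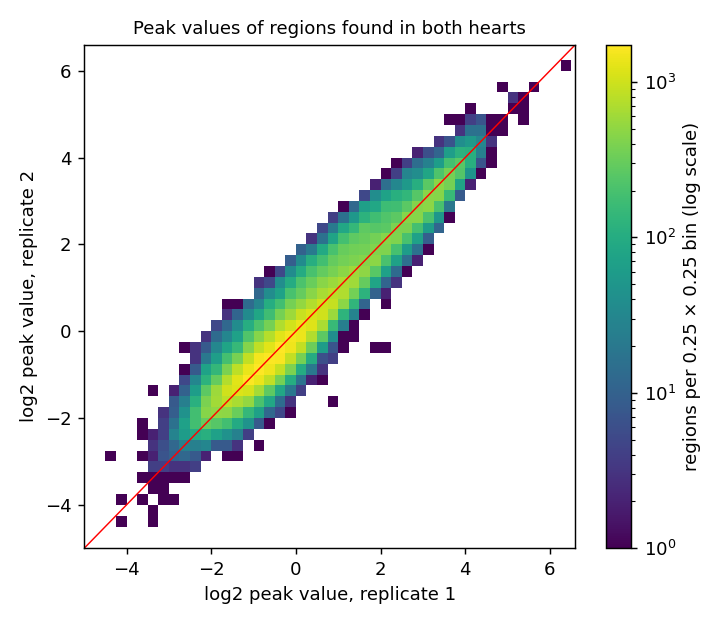
Peak values of the 92536 regions open in both hearts, with the log2 peak value of replicate 1 on the horizontal axis and of replicate 2 on the vertical axis. Colour gives the number of regions per bin on a log scale and the red line marks equal values; the Pearson r across regions was 0.951.

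Peaks absent from the other heart had low values. With neither a peak nor a base listed at a false discovery rate (FDR) under 0.05 in the other heart, 26467 peaks of replicate 1 and 20275 of replicate 2 stood alone. Their median values were 0.339 and 0.333, against 0.683 and 0.724 for all peaks. In replicate 1 the highest lay in an intron of Nfix on chromosome 8 (84789921 to 84790120) at 1.85, at the promoter of Pdlim4 at 1.64 and in an intron of Tns1 at 1.60. In replicate 2 the highest lay in an intron of Cx3cr1, with Csrnp1 as the nearest gene start, on chromosome 9 (119970261 to 119970460) at 2.13, in intergenic DNA near Efcab14 at 1.89 and in an intron of Xxylt1 at 1.86. With 1 animal behind each, these differences have no replicate check.

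Promoters took up a far larger share of the peaks than of the genome. Peak centres fell within 1 kb of a transcription start site (TSS) of a protein-coding gene in 25.4% ± 1.65 (SD, n = 2) of peaks, a class that makes up 3.70% of the genome, a ratio of 6.86. The exact binomial 95% intervals were 24.0% to 24.5% in replicate 1 and 26.3% to 26.8% in replicate 2, and they cover counting error only. Exons held 4.30% ± 0.195 of peaks, introns 33.0% ± 1.10 and intergenic DNA 37.3% ± 0.360, while 60.1% of the genome is intergenic. Promoter regions open in both hearts also had higher values than distal ones, with a median mean value of 2.29 against 0.790. Of 21911 protein-coding genes, 14536 (66.3%) had a peak within 500 bp of a TSS in both hearts, 6705 in neither and 670 in 1 heart.

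Promoters of heart muscle genes were open more often than those of other protein-coding genes. In the list of cardiomyocyte contractile genes, 19 of 21 had a promoter peak in both hearts (90.5%, adjusted p = 0.0303, two-sided Fisher's exact test, Benjamini-Hochberg over 22 lists). The highest values there were 16.1 ± 2.60 (SD, n = 2) for Myom1, an M-band protein gene, 14.6 ± 1.56 for the tropomyosin gene Tpm1 and 2.09 ± 0.241 for Ldb3. Ion handling and conduction genes had promoter peaks in 17 of 18 cases (adjusted p = 0.0178, Fisher's exact test). They were led by the potassium channel gene Kcnj2 at 9.27 ± 0.778, the calcium pump gene Atp2a2 at 8.45 ± 2.09 and the potassium channel gene Kcnh2 at 3.10 ± 0.704. All 21 genes of fatty acid oxidation and muscle mitochondria had promoter peaks (adjusted p = 0.00192, Fisher's exact test), with Acsl1, which activates long-chain fatty acids, at 14.96 ± 0.780, the ADP/ATP carrier gene Slc25a4 at 12.3 ± 0.375 and Acadm at 11.96 ± 0.593. Of 20 cardiac transcription factor genes, 19 had promoter peaks (adjusted p = 0.00881, Fisher's exact test). Esrra reached 18.2 ± 0.897, Hey2 13.8 ± 0.464 and Mef2a 12.03 ± 1.68, and Hand1 was the member with no promoter peak in either heart. The calls of the contractile and ion handling lists ended with the shorter peak list (adjusted p = 0.581 and 0.577), in the upper 50% of peaks by value (0.122 and 0.0966) and with the 5' end of each gene only (0.267 and 0.101, Fisher's exact tests). That of the contractile list also ended with a 1 kb window and without replicate 1 (adjusted p = 0.0550 and 0.0512), and that of the cardiac transcription factors with the 5' end only (0.168, Fisher's exact tests) and against genes matched on promoter CpG ratio, a comparison chosen after seeing the data (0.127, permutation test).

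Open promoters had low median values in the contractile list and in several lists of other cell types, a difference that was not tested. Where called, the median promoter value was 1.46 in the contractile list and 1.49 in the ion handling list, against 5.80 over all genes with a promoter peak in both hearts. The cardiac transcription factor list had a median of 4.10 and the fatty acid oxidation list 5.47, while endothelial genes had 2.21, fibroblast genes 1.95, smooth muscle and pericyte genes 1.66, skeletal muscle genes 0.837, macrophage and lymphocyte genes 0.799 and neuronal genes 0.592. Myl2, the ventricular myosin light chain gene, had a promoter value of 1.54 ± 0.0641 (SD, n = 2) and 17 distal peaks within its domain, meaning the gene and 50 kb on each side. Nkx2-5, a cardiac homeobox gene, had 1.87 ± 0.327 and 16 distal peaks.

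The lists of heart chambers and cardiac stress did not pass the test. Of 12 atrial genes 8 had a promoter peak in both hearts (adjusted p = 1), of 9 ventricular genes 7 (adjusted p = 0.858) and of 10 stress response genes 7 (adjusted p = 1, Fisher's exact tests). Among atrial genes, the promoter of Myl4, the atrial essential light chain, reached 17.4 ± 1.81 (SD, n = 2), Pam 6.41 ± 1.36 and Nr2f1 1.69 ± 0.366, and Myl7, the atrial regulatory light chain, had no promoter peak in either heart. Among stress genes Hmox1 had 8.21 ± 0.593, Mt1 5.69 ± 0.168 and Ccn2 4.22 ± 0.679, and the skeletal actin gene Acta1 had none.

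Of 7 lists of other cell types of the heart, 3 had promoter peaks more often than other genes and 4 did not pass. Promoter peaks in both hearts were found at 19 of 20 endothelial genes (adjusted p = 0.00881), all 16 fibroblast genes (adjusted p = 0.00626) and all 13 smooth muscle and pericyte genes (adjusted p = 0.0130, Fisher's exact tests). Vwf, the von Willebrand factor gene, had a promoter value of 5.18 ± 0.838 (SD, n = 2), Eng 4.96 ± 0.239 and the VEGF receptor gene Flt1 4.08 ± 0.921. The collagen gene Col1a1 had 6.99 ± 1.18, Pdgfra 6.36 ± 0.642 and the fibronectin gene Fn1 6.08 ± 0.826, while Smtn had 7.11 ± 0.464, Myh11 3.06 ± 0.730 and Kcnj8 3.02 ± 0.108. Macrophage and lymphocyte genes (11 of 17, adjusted p = 1), adipocyte genes (5 of 12, adjusted p = 0.178), epicardial genes (6 of 10, adjusted p = 0.858) and Schwann cell genes (8 of 10, adjusted p = 0.703) did not pass Fisher's exact test. Of these lists' members, Fcgr3 had 4.62 ± 0.608, Lipe 5.17 ± 0.0463, Aldh1a2 2.92 ± 0.0416 and the myelin gene Prx 11.9 ± 1.18. Ptprc, the pan-leukocyte marker, and Adipoq, the adiponectin gene, had no promoter peak in either heart. In the upper 50% of peaks by value the fibroblast and smooth muscle lists did not pass (adjusted p = 0.399 and 1), nor did they in the shorter list (0.0682 in each), and with the 5' end of each gene only the fibroblast and endothelial lists did not (0.0750 and 0.168, Fisher's exact tests). Macrophage and lymphocyte genes were lower in the shorter list (adjusted p = 0.0199) and adipocyte genes with the 5' end only (0.0382, Fisher's exact tests).

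Of 5 lists of marker genes of other tissues, 4 had promoter peaks less often than other genes. Only 1 of 20 hepatocyte genes, Apoh at 1.67 ± 0.312 (SD, n = 2), had one in both hearts (adjusted p = 3.05e-07, Fisher's exact test), and the albumin gene Alb had neither a promoter peak nor a distal peak. The germ cell list had 1 of 16, Dazl at 6.63 ± 0.938 (adjusted p = 9.63e-06, Fisher's exact test), with none at Ddx4 or at the protamine gene Prm1. In the erythroid list 2 of 12 had one (adjusted p = 0.00261, Fisher's exact test), Epor at 2.09 ± 0.129 and Tfr2 at 1.22 ± 0.0633, and the globin genes Hba-a1 and Hba-a2 had none. The skeletal muscle list had 7 of 20 (adjusted p = 0.0130, Fisher's exact test), led by Mylpf at 7.85 ± 1.13, and the myogenic factors Myod1 and Myog had none. Neuronal genes, with 11 of 18, did not pass (adjusted p = 0.809), but were lower in the upper 50% of peaks by value (adjusted p = 0.00394), and the skeletal muscle call ended with a 1 kb window (adjusted p = 0.343, Fisher's exact tests). The erythroid and skeletal muscle calls also ended against genes matched on promoter CpG ratio (adjusted p = 0.452 and 0.253, permutation test).

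Genes used in most cells and genes that respond to time of day or to stimuli were open throughout. All 20 housekeeping genes (adjusted p = 0.00253), all 17 circadian clock genes (adjusted p = 0.00480) and all 16 immediate early genes (adjusted p = 0.00626, Fisher's exact tests) had a promoter peak in both hearts, with median values of 9.86, 12.2 and 10.2. Rplp0, a ribosomal protein gene, had 22.1 ± 4.25 (SD, n = 2), the clock output gene Tef 20.3 ± 0.548, Per3 15.04 ± 1.38, Per2 14.4 ± 0.407, Jund 16.9 ± 0.0329, Egr1 16.5 ± 0.536 and Jun 15.7 ± 0.816. Against genes matched on the CpG ratio of the promoter, the housekeeping, circadian and immediate early lists no longer passed (adjusted p = 0.101, 0.173 and 0.466, permutation test). When only the 5' end of each gene was used, 5 lists were called higher in place of 10.

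Distal peaks, over 1 kb from any TSS, were counted in each gene's domain and compared with 10000 random gene lists of matched domain length. Immediate early genes had a mean of 12.9 distal peaks against 4.10 in matched lists (adjusted p = 0.0044, two-sided permutation test). Circadian clock genes had 10.8 against 5.57 (adjusted p = 0.0044), smooth muscle and pericyte genes 10.2 against 5.84 (adjusted p = 0.0235) and endothelial genes 10.9 against 6.43 (adjusted p = 0.0385, permutation tests). Jund had 15 distal peaks within its domain, Egr1 11, Tef 14, Kcnj8 13, Flt1 22 and Eng 16. Cardiac transcription factor genes had 12.5 against 7.17 (adjusted p = 0.0546), contractile genes 8.43 against 6.10 (adjusted p = 0.129) and ion handling genes 11.7 against 7.94 (adjusted p = 0.111), none of which passed the permutation test. Without replicate 2, 8 lists passed in place of 4, with the contractile, cardiac transcription factor, ventricular and stress response lists added (adjusted p = 0.0333, 0.0333, 0.0198 and 0.0473, permutation test). In the upper 50% of peaks by value 6 lists passed, with the contractile and cardiac transcription factor lists (adjusted p = 0.0477 in each) and the housekeeping list (0.0440) added, and housekeeping genes (adjusted p = 0.0594 in the main comparison) also passed in the shorter list (0.0370) and with promoter peaks counted too (0.00587, permutation tests). The smooth muscle call ended with domains of 20 kb or 100 kb and in the upper 50% of peaks by value (adjusted p = 0.136, 0.144 and 0.0974), and with promoter peaks counted too both it and the endothelial call ended (0.0572 in each, permutation tests). No list had fewer distal peaks than matched lists at an adjusted p under 0.05 by the permutation test, and 0 were lower at an unadjusted p under 0.05.

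**Figure D2:**
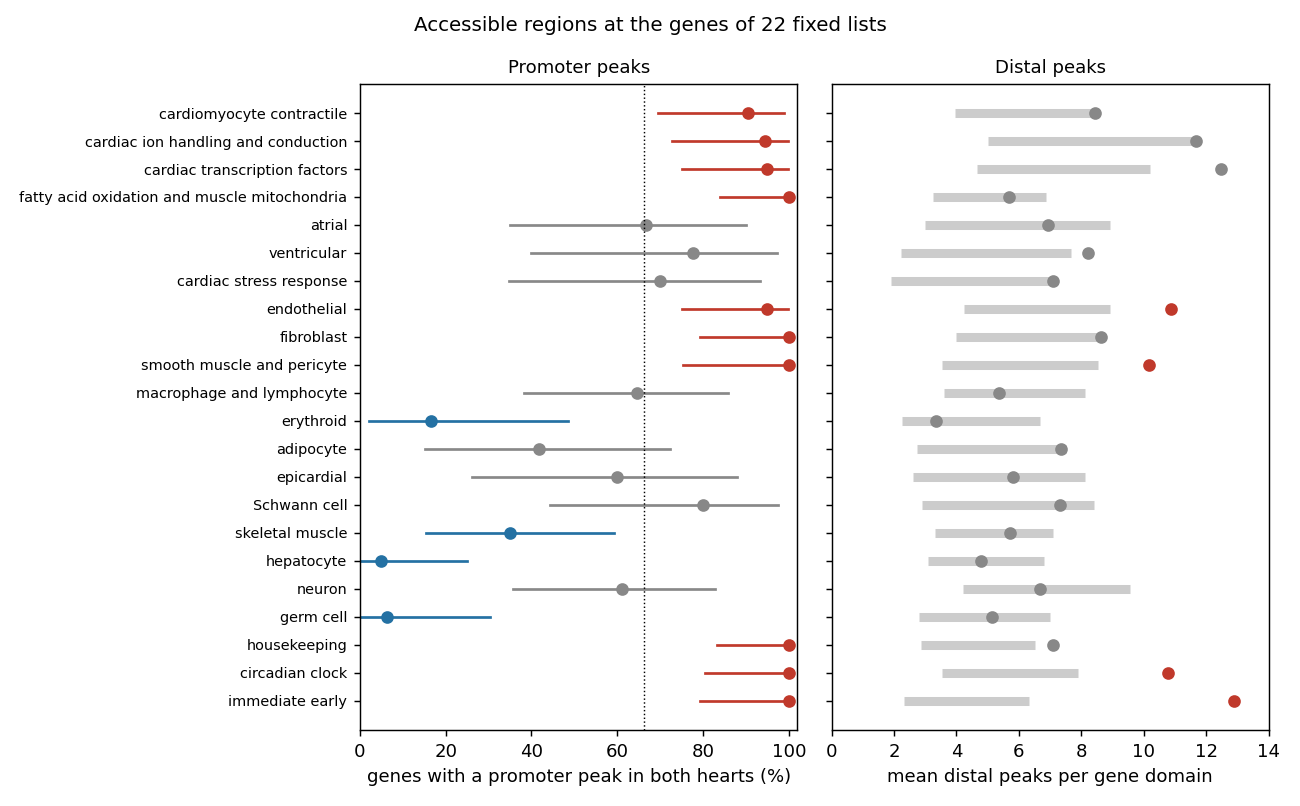
Accessible regions at the genes of 22 lists. The left panel gives the percent of each list with a promoter peak in both hearts, with exact binomial 95% intervals as lines and the mean of other genes as a dotted line (66.3%); the right panel gives the mean number of distal peaks per gene domain, with the central 95% range of 10000 matched random lists as grey bars. Red and blue mark lists higher or lower at an adjusted p under 0.05, and 4 lists, immediate early genes highest at 12.9, passed in the right panel.

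The genes with the most distal peaks had long domains. Gse1 had 77 within 453 kb, the axon guidance gene Nav2 66 within 801 kb, Camta1 63, Tns1 58 within 314 kb, the nuclear receptor gene Rora 56, Kalrn 53 and the T-cadherin gene Cdh13 51. Gm20388, with 388 within 4535 kb, Fgfr2, with 145 within 3061 kb, and Gm37240, with 58, have annotated bodies that span other genes, so their counts include the neighbours' peaks.

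Footprints are short stretches within open DNA that were cut less than their surroundings, as happens where a protein covers the DNA. The deposited lists held 339570 footprints in replicate 1 and 328008 in replicate 2, with a median width of 10 bp in each. Of these, 84.9% and 87.4% lay in peaks. A mean of 51.7% ± 0.247 (SD, n = 2) overlapped a footprint of the other heart. Of all footprints of replicates 1 and 2, 43.4% and 44.2% overlapped those footprints of the other heart that lay wholly inside its peaks, against 24.4% and 25.2% after the latter were moved at random within the same peaks. Footprints of both hearts numbered 161602, and 43.3% of them lay within 1 kb of a TSS.

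Consensus sequences of 30 transcription factors or families were counted in the footprints of both hearts and in the rest of the open regions. NRF1, an activator of mitochondrial and housekeeping genes, had the highest ratio of matches per kb, a log2 ratio of 6.64, with 417 matches in footprints and 19 elsewhere. CTCF, the chromatin loop and insulator protein, had 5182 matches in footprints and 501 elsewhere, a log2 ratio of 5.58. Next came ZNF143 at 4.11 (72 against 19 matches), SP/KLF at 3.83 (5368 against 1755) and CREB at 3.69 (723 against 259). Values from each heart alone were 6.65 and 6.33 for NRF1, 5.13 and 5.47 for CTCF, and 3.54 and 3.50 for CREB. In all, 13 motifs were denser in footprints and 8 less dense at an adjusted p under 0.05 (exact binomial test, Benjamini-Hochberg over 30 motifs). With replicate 2 alone 4 were less dense and at 10 bp or wider 12. In distal regions alone the log2 ratio was 5.45 for NRF1, 5.78 for CTCF and 2.78 for ZNF143 (4 against 3 matches). There SP/KLF was at 2.83 and CREB at 2.55.

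The motifs of several cardiac factors were not denser in the footprints found in both hearts. The lowest log2 ratios were −1.27 for FOX (adjusted p = 1.7e-35), −1.22 for GATA (adjusted p = 2.38e-27), −0.99 for SOX (adjusted p = 0.000519), −0.83 for TBX (adjusted p = 5.33e-07) and −0.67 for SPI1, a leukocyte factor with 7 matches in footprints, which did not pass (adjusted p = 0.280, exact binomial tests). For MEF2 the log2 ratio was −0.48 (adjusted p = 0.000392, exact binomial test) in footprints of both hearts, 0.34 in replicate 1 alone and −0.18 in replicate 2 alone. In the footprints of replicate 1 alone MEF2 and TEAD, at 0.17, passed as denser (adjusted p = 0.000503 and 0.0120, exact binomial tests). Without replicate 1 neither MEF2 nor SOX passed (adjusted p = 0.191 and 0.159, exact binomial tests). TEAD at −0.11 and NKX2-5 at −0.19 did not pass in the footprints of both hearts (adjusted p = 0.211 and 0.104), but were less dense in footprints of 10 bp or wider, a setting chosen after seeing the data, at −0.32 and −0.26 (adjusted p = 0.000706 and 0.0451), as was TEAD in footprints not widened, at −0.34 (adjusted p = 0.000467, exact binomial tests). Against shuffled consensus sequences in the same footprints, matches were more frequent for FOX, SOX, SPI1 and MEF2, with log2 ratios of 0.41, 0.95, 2.32 and 2.88, and less frequent for GATA and TBX, with −0.34 and −0.82. The size of these ratios depends on the draw of shuffles. Shuffled matches averaged 138.3 per shuffle for TBX and 182.4 for GATA here, while a second draw of 10 shuffles held 937 and 2199 in total.

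**Figure D3:**
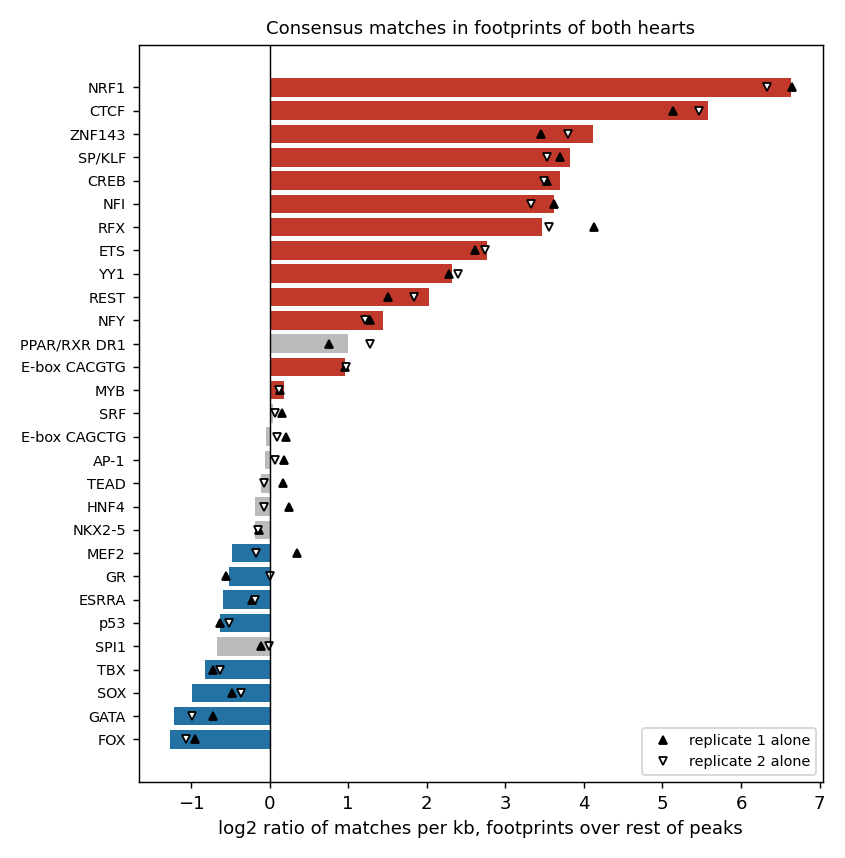
Consensus matches per kb in footprints of both hearts over those in the rest of the open regions, as log2 ratios per motif (bars), with each heart's own footprints as triangles. Red and blue bars mark motifs denser or less dense at an adjusted p under 0.05 and grey bars those that did not pass; NRF1 (6.64) and CTCF (5.58) were highest, FOX (−1.27) lowest, and HNF1, with 1 match, is not drawn.

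Peaks on the X chromosome, of which males carry 1 copy, had lower values than autosomal peaks in both hearts. The median X value was 0.574 times the autosomal median in replicate 1, a log2 ratio of −0.80, and 0.565 times in replicate 2, a log2 ratio of −0.82 (p = 1e-05 in each, the smallest that 100000 resamples of the two-sided permutation test can give). Median X values were 0.396 and 0.416, and the lowest autosomal medians were 0.600 on chromosomes 3 and 13 in replicate 1 and 0.647 on chromosome 13 in replicate 2. X also held fewer peaks, with 18.1 and 18.9 per Mb against 49.9 and 49.5 on autosomes. Y held 70 and 117 peaks. The labels give the strain name B6CASTF1/J and do not otherwise spell out the direction of the cross. The parental strain of the X was not established here, and whether strain differences from the reference lower its values was not tested. Among peaks in the upper 50% of each library by value, the ratio turned round, to a mean log2 ratio of 0.084, with 0.12 in replicate 1 (p = 0.0167) and 0.048 in replicate 2 (p = 0.346, permutation tests).

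**Figure D4:**
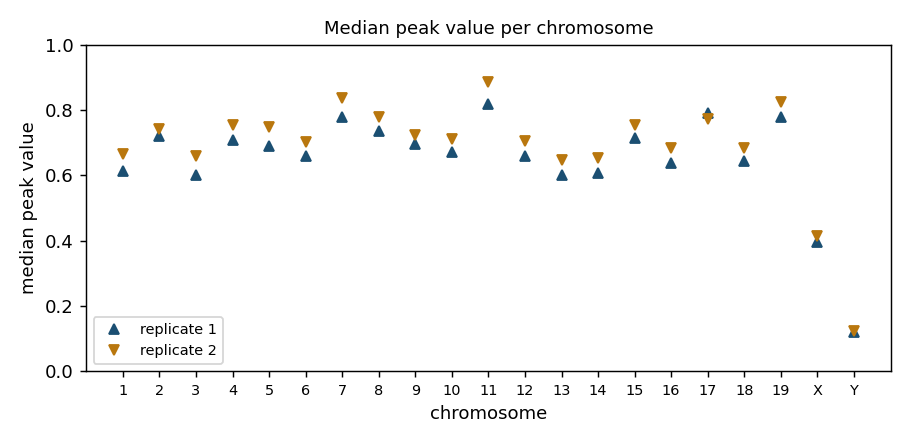
Median peak value per chromosome in replicate 1 (upward triangles) and replicate 2 (downward triangles), in the authors' signal units. X medians are 0.396 and 0.416, below those of each of the 19 autosomes in both hearts.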

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

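The matching on CpG ratio and the reading of the lists that lost their call under it, and the footprint ratio less that of shuffled consensus sequences are tests chosen only after results were seen, as were the 95% intervals and the values of all 5 strength groups set beside the planned tests of the motifs. No biological explanation was tested, since the series has 1 group, and differences between the 2 animals stay open throughout.

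Signal outside the peak lists came from the per-base FDR lists, which the comparisons above use only to define peaks of one library alone. Bases at an FDR of 0.001 or below that lay in no peak of the longer list covered 12.8 Mb in replicate 1 and 10.2 Mb in replicate 2. Of these bases 65.5% and 71.9% lay within 150 bp of a peak.

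Differences between the hearts were weighed as the first pattern. The log2 ratio of their values varied 6.202 times as much as Poisson counts of value over step would give, but this decides nothing about counting error, since animals differ beyond technical noise and the reading of a step as 1 count is not stated. Bin means over 50 bins of GC content accounted for 9.83% of the whole variance (11.7% of that beyond such Poisson counts). Those over bins of the strength of the region accounted for 1.499% (1.79%). This argues against a shift of the ratio with GC content or strength as the main cause. Bin means cannot see scatter that widens in both directions, so they decide nothing about that. The SD of the log2 ratio was 0.48 in distal regions, with a median value of 0.790, and 0.36 in promoter regions, with 2.29. The direction followed GC in part, with a median log2 ratio of 0.22 in the fifth of regions with the lowest GC and −0.14 in the fifth with the highest, so a difference in library chemistry may add to it. Open are counting error, scatter that changes with strength or GC content, and a difference between the animals, in cell make-up or in handling. With 1 library per animal these are not separated.

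Gene lists with more promoter peaks than other genes were the second pattern. CpG-rich promoters are open in most tissues, so the CpG content of the promoter is a candidate explanation. Of the 10 lists called higher, 6 were still called against CpG-matched genes: contractile (90.5% against 42.6%), ion handling (94.4% against 60.6%), fatty acid oxidation (100% against 69.0%), endothelial (95% against 61.7%), fibroblast (100% against 52.4%) and smooth muscle (100% against 61.5%). This cannot decide about CpG content, since the ratio was measured at the 5' end of each gene, while a peak at any TSS counted. With the 5' end only, the contractile, ion handling, endothelial and fibroblast calls against all other genes ended (adjusted p = 0.267, 0.101, 0.168 and 0.0750, Fisher's exact tests). The fatty acid oxidation and smooth muscle calls stayed. For the cardiac transcription factor, housekeeping, circadian and immediate early lists the log2 odds ratio fell from 2.72 to 1.81, from 4.38 to 2.80, from 4.15 to 2.60 and from 4.07 to 1.97, since matched genes averaged 86.7%, with ranges up to 95% for the first 2 lists and up to 100% for the others, and the smaller difference no longer passed. For these 4 lists, of 16 to 20 genes, CpG content and a property of the genes cannot be told apart.

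Footprint ratios of cardiac factor motifs, with a median log2 ratio of −0.54 over MEF2, GATA, TEAD, NKX2-5, ESRRA and TBX in footprints of both hearts (95% interval of the mean −1.002 to −0.14), were the third pattern, which leaves out SRF, at 0.04. With the footprints of 1 heart the median was −0.18 in each and the intervals of the mean included 0 (−0.68 to 0.25 in replicate 1 and −0.75 to 0.019 in replicate 2): GATA and TBX alone stayed less dense in both, ESRRA did so in neither (adjusted p = 0.158 and 0.320, exact binomial tests) and MEF2 was denser in replicate 1. In the fifth of distal regions with the highest values the median was −0.25 (95% interval of the mean over the 6 motifs −0.64 to −0.016, with SRF −0.56 to −0.051), below the planned bound of 0 for footprints being called mainly in strong regions, but that stays open, since the motifs were named after their ratios were seen and the medians over 5 equal groups of regions from the lowest values up went both ways (−0.38, 0.22, 0.05, −0.35 and −0.25). The density of the motifs in distal regions over flanks 1.5 kb away, with a median log2 ratio of 0.012, decides nothing about scarcity in open regions, which would lower matches in footprints and in the rest of the regions alike. Base composition stays open: the motifs exceeded shuffled consensus sequences within footprints by a median of 0.73, a planned comparison that was not taken to decide because it does not use the rest of the regions, and with the ratio of shuffled sequences taken off the median was −0.14 (95% interval of the mean −0.48 to 0.31).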

How the results depend on the processing

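Footprints of 10 bp or wider, merged runs of listed bases and genes matched on promoter CpG ratio were alternatives chosen after seeing the data, and the planned upper 50% by footprint statistic was not run, since the footprint lists hold none. The X against autosome ratio stayed below 0 and past its threshold with the shorter peak list, with promoter or distal peaks only and with either library left out (−0.82 and −0.80). Only the upper 50% by value gave the opposite sign, 0.084 (0.12 and 0.048 in the hearts), and that setting keeps, on every chromosome alike, only peaks above 1 value per library, so it removes the low X peaks being compared. Single lists and motifs kept direction and side of the threshold in 136 of the promoter comparisons, 146 of the distal ones and 161 of the motif ones, and lost a call without changing direction in 22, 5 and 12. Where no cause is given, the cause was not tested. The depth in reads is unknown, and what it limits was not tested.

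Mean peaks per library fell from 125591 to 63135 in the upper 50% by value and 79268 in the shorter list, by construction. Replicate 1 alone had 126037 and replicate 2 alone 125145. Overlap of the hearts' peaks moved from 76.8% to 86.6% in the upper 50% by value, 80.6% in the shorter list and 79.6% for merged runs, and to 63.5% when 50% of both regions had to overlap. Footprints fell to a mean of 174358 at 10 bp or wider; their overlap moved from 51.7% to 60.01% at that width, 50.7% inside peaks only and 38.1% when 50% of both had to overlap. The promoter share of peaks moved from 25.4% to 36.1% in the upper 50% by value and 32.4% in the shorter list. It was 31.3% with a 2 kb window and 19.4% with a 500 bp window. With replicates 1 and 2 alone it was 24.2% and 26.6%. Peaks of one library alone fell from 46742 to 2718 in the upper 50% by value.

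Lists called higher by promoter peaks numbered 10, but 6 each in the upper 50% by value, in the shorter list and against CpG-matched genes. They numbered 5 with the 5' end of the gene only, 10 with replicate 1 alone and 9 with replicate 2 alone. Lists called lower numbered 4, but 2 against CpG-matched genes. By distal peaks 4 lists were higher, but 6 in the upper 50% by value, 5 in the shorter list, 3 each with 20 kb domains, 100 kb domains and promoter peaks counted, 4 with gene density matched too, and 4 and 8 with 1 library (8 without replicate 2). Motifs denser in footprints numbered 13, but 25 against shuffled consensus sequences, 16 with replicate 1 alone and 14 with replicate 2 alone. Motifs less dense numbered 8, but 12 at 10 bp or wider, 10 not widened, 6 in distal footprints, 3 against shuffled sequences, and 4 and 6 with 1 library (4 without replicate 1). AP-1 was gained as less dense not widened (−0.53, adjusted p = 1.07e-20), and AP-1 (−0.37, 1.33e-11), E-box CAGCTG (−0.21, 3.7e-05), TEAD and NKX2-5 at 10 bp or wider (exact binomial tests). The opposite call was gained in distal footprints, where AP-1 (0.16, adjusted p = 0.00178) and E-box CAGCTG (0.21, 4.13e-05) were denser (exact binomial tests). There ETS (0.64, adjusted p = 0.0723) and MYB (0.037, 0.839) were no longer called denser (exact binomial tests). With replicates 1 and 2 alone AP-1 was at 0.18 and 0.073 and E-box CAGCTG at 0.20 and 0.093, so neither motif has a settled direction.

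Log2 odds ratios of promoter lists changed sign only in lists called in no direction in the main comparison. With replicates 1 and 2 alone the values were −0.17 and 1.87 for atrial genes and 0.092 and 0.12 for macrophage and lymphocyte genes. For epicardial genes they were −0.56 and 0.034. Against CpG-matched genes atrial was 0.23 and macrophage and lymphocyte 1.36. In the upper 50% by value stress response and Schwann cell genes were each at −0.044, and in the shorter list ventricular genes were at −0.45 and Schwann cell genes at −0.21. Ventricular genes were at −0.34 with the 5' end only. A 200 bp window gave 0.073 for atrial and −0.31 for stress response genes, and a 1 kb window 0.68 for epicardial and 0.61 for neuronal genes.

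Log2 ratios of distal peaks changed sign likewise. Macrophage and lymphocyte genes were at 0.037 in the upper 50% by value, 0.052 with 20 kb and 0.011 with 100 kb domains, 0.075 with promoter peaks counted, and −0.0045 and 0.098 with 1 library. Erythroid genes were at 0.18 with 100 kb domains and 0.10 with promoter peaks counted. Epicardial genes were at −0.21 in the upper 50% by value, −0.064 in the shorter list and −0.051 with promoter peaks counted, and neuronal genes at −0.23 in the upper 50% and −0.039 with promoter peaks counted. Germ cell genes were at −0.61 with 20 kb domains and −0.29 with promoter peaks counted, and hepatocyte genes at 0.064 and 0.20 with 1 library.

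Motif log2 ratios changed sign most often against shuffled consensus sequences, a comparison within footprints that leaves out the rest of the regions: MEF2 2.88, SPI1 2.32, AP-1 2.26, ESRRA 1.89, the glucocorticoid receptor 1.81, E-box CAGCTG 1.51, TEAD 1.16, SOX 0.95, HNF4 0.89, FOX 0.41, NKX2-5 0.29, HNF1 −0.14 and MYB −1.61. In distal footprints E-box CAGCTG was at 0.21, AP-1 at 0.16, HNF4 at 0.048 and TEAD at 0.026. Footprints not widened gave 0.094 for E-box CAGCTG, and widening by 10 bp gave −0.026 for SRF. With replicates 1 and 2 alone the values were 0.34 and −0.18 for MEF2, 0.17 and −0.067 for TEAD, and 0.24 and −0.067 for HNF4. In the same order they were 0.18 and 0.073 for AP-1, 0.20 and 0.093 for E-box CAGCTG, and −0.55 and 0.0052 for the glucocorticoid receptor.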

Other observations

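Gene families chosen by symbol after the lists had been analysed differed in how often their promoters were open in both hearts. Promoter peaks were found at 11 of 1134 olfactory receptor genes (0.970%, exact binomial 95% interval 0.485% to 1.73%) and at 1 of 330 vomeronasal receptor genes. Keratin and keratin-associated genes had 6 of 113 and Hox genes, which pattern the body axis, 13 of 39. All 37 genes of complex I subunits named Nduf had one, with a median value of 9.05, as had 77 of 79 ribosomal protein genes (9.68) and 39 of 40 proteasome subunit genes (8.02). Zinc finger genes named Zfp had 344 of 394 (87.3%) and solute carriers 266 of 371 (71.7%).

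Consensus matches in distal regions were also set beside flanks 1.5 kb away that held no peak. CTCF matches were 83.5 times as dense in the regions, NFI 12.4 times, SP/KLF 7.008 times and NRF1 5.61 times. The leukocyte factor SPI1 was at 4.51 times, with only 48 against 18 matches, ETS at 3.43 times and CREB at 3.14 times. The E-box CAGCTG was at 2.94 times, MEF2 at 2.87 times, the glucocorticoid receptor motif at 2.53 times and AP-1 at 2.05 times. FOX was at 0.981 times, NKX2-5 at 1.03 times, SRF at 0.923 times and TBX at 0.663 times.

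The largest differences between the hearts, among regions open in both with a mean value of 2 or more, were chosen after seeing the data and have no replicate check. An intron of Zc3h7a on chromosome 16 (11143861 to 11143960) had 4.08 in replicate 1 and 0.730 in replicate 2. This region lies beside a far higher one (11144171 to 11144320) that hardly differed, with 35.9 and 37.0. The difference thus concerns the flank of a strong signal and not the locus as a whole. Intergenic DNA far from Myom2 on chromosome 8 had 3.67 and 0.772. The Fgfr1op promoter had 4.50 and 1.43. In the other direction, intergenic DNA on chromosome 11 near Eif1 had 1.09 and 3.93. Intergenic DNA on chromosome 10 had 1.56 and 5.65, and an intron of Aim2 on chromosome 1 had 1.05 and 3.68. The region near Eif1 had a share of soft-masked repeat sequence of 0.825, the highest among these regions. Whether this bears on its difference was not tested. More than 2-fold differences were higher in replicate 2 in 3199 regions and higher in replicate 1 in 356. Promoters made up 5.85% of the former and 20.5% of the latter, both below the 27.0% of all regions open in both hearts.

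Between the hearts, the median log2 ratio of replicate 2 to replicate 1 over promoter peaks was 0.23 for 19 endothelial genes, 0.41 for 5 adipocyte genes, −0.29 for 19 cardiac transcription factor genes and −0.24 for 17 ion handling genes, beside −0.08 for all promoter regions. It was −0.07 for the contractile list and for the fatty acid oxidation list, −0.02 for fibroblast genes and 0.04 for smooth muscle and pericyte genes. The widest single values were −1.21 for Irx4, −0.92 for Clock, −0.83 for Trdn and 0.90 for the mesothelial gene Msln. The SD over all promoter regions was 0.36, and the difference between lists was not tested.

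The 50 regions with the highest values were 74.0% promoters, beside 27.0% of all regions, and their median share of soft-masked repeat sequence was 0%, beside 3.60% of all regions. Copy number of these regions in the genome was not tested.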
